A study of Mus musculus with 6 samples.

How the data were processed

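A total of 6 libraries of BUMPT cells were analysed, 3 labelled NC and 3 labelled tRF-Val, with groups and replicate numbers taken from the sample titles. RNA was extracted with Trizol and libraries were made with a stranded kit that marks the second strand with dUTP, per the labels' protocols. The same protocol text describes joint tissue, while the labels of each sample name a kidney cell line; the labels of the samples were followed here. Per the submitters' processing notes, cutadapt, HISAT2 2.1.0 and StringTie were used, and the build named there is the human GRCh38. The annotation release, filters and settings are not given in the sources used here.

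The deposited table holds 1 signal value per transcript and library, an abundance that the authors scaled to the library; whether it is FPKM or TPM is not stated. The values are not read counts, so no count model was used and depth is unknown. Of 30813 rows, the first 21603 carry mouse transcript IDs and the 9210 rows from row 21604 on carry human ones. The human rows were not used. Mouse IDs were matched without their version to GENCODE M21 on GRCm38: 21558 matched, 20488 of them with the same version, and 45 did not. Of the mouse rows 21530 belong to protein-coding genes. Each mouse row has a mean of at least 0.5 in 1 of the groups, so lower transcripts are missing from the gene sums.

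Values of all transcripts of a gene symbol were added, giving 11236 symbols, of which 5779 had 1 transcript and 7 covered more than 1 gene ID. Genes with a mean of at least 1 over the 6 libraries were kept. Log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3, with trend and robust empirical Bayes moderation, both groups in 1 fit and no covariate. P-values are two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so none is reported.

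Before the data were examined, 31 gene lists and the rule for named genes were written. That rule takes Apaf1, up to 12 genes with the largest rise and up to 12 with the largest fall among genes that passed and whose groups did not overlap, and up to 4 members with the smallest p of each list that passed and of intrinsic apoptosis. Here 6 and 12 genes met it. The 25 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes, while fry asks whether the members move, on balance, one way.

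Alternatives written before the data were examined were pseudocounts of 0.1 and 0.01, no filter and a stricter one, median and quantile scaling, limma without trend and without robust moderation, library quality weights, the replicate number as a block, each library left out in turn, transcripts in place of genes and a 2-fold threshold. Alternatives chosen after seeing the data were removal of each library's loess trend (span 0.3) with transcript length, or with length and GC content, rescaling without mitochondrial transcripts, NC 3 left out together with that correction, and a second method for the weights. Length and GC content came from M21 transcripts, weighted by abundance; GC content was missing for 5 tested genes, which were given the median.

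The fit was tested on simulated data with the means of the 10405 genes and a spread that was a smooth function of the mean. Noise was independent and equal between libraries, so no library stood apart as NC 3 does, and no length trend was present. Of 200 genes changed by 1, 2 and 3 on the log2 scale the fit recovered 79%, 100% and 100%, and it called 2, 10 and 15 unchanged genes. On the real libraries it may recover fewer. Chosen after seeing the data, 7-base words in 3' UTRs were tested with 1000 permutations, and lists were set against 10000 random lists matched on length and GC content, with each member replaced by 1 of its 100 nearest genes. These steps were also tested on simulated data. Some single genes are not reported here by name, although they remain in the counts.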

Results

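RNA sequencing was compared between 2 groups of BUMPT cells, a mouse line of renal proximal tubular epithelial cells. One group carried the label NC and the other tRF-Val, after tRF-Val-TAC-004, a fragment of a valine transfer RNA; each had 3 libraries. The labels do not spell out NC and do not say whether the fragment was added or blocked, so the groups are named here as labelled. The stated purpose was to find a downstream target of the fragment in apoptosis, and the series names Apaf1. Abundance was given per transcript, scaled to the library, and was added over the transcripts of each gene. The sum of the values over mouse transcripts was 387611 to 389669 in the NC libraries and 421201 to 444539 in the tRF-Val libraries. These sums do not give the number of reads, so the depth of each library is unknown. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Fold changes are tRF-Val minus NC on the log2(value + 1) scale, which understates changes of low genes.

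Gene values of NC 1 and NC 2 had a Pearson r of 0.974 across 10405 genes, which are not independent replicates, and the 3 tRF-Val libraries had r of 0.953 to 0.962 with one another. NC 3 stood apart, with r of 0.903 to NC 1 and 0.915 to NC 2. Both of those NC libraries were closer to each tRF-Val library, with r of 0.922 to 0.956, than to NC 3. Between NC 3 and the tRF-Val libraries r was 0.843 to 0.875. The libraries thus did not group by label alone. The first principal component held 52.9% of the variance and placed NC 3 at -69.2, against -7.87 and -10.7 for NC 1 and NC 2. It placed tRF-Val 1, 2 and 3 at 17.7, 38.3 and 31.8. Mitochondrially encoded transcripts made up 17.5% of the values in NC 3, 6.32% in NC 1 and 6.58% in NC 2, against 5.29%, 3.67% and 3.16% in tRF-Val 1, 2 and 3. No 2 libraries held identical values.

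Apaf1, which encodes the scaffold on which caspase-9 is activated in the intrinsic pathway of apoptosis, had a mean value of 2.43 ± 0.475 (SD, n = 3) in NC and 0.558 ± 0.113 (SD, n = 3) in tRF-Val. Each NC library (2.86, 1.92 and 2.51) lay above each tRF-Val library (0.683, 0.461 and 0.532). The log2 fold change was -1.13 (SE 0.175). In limma's moderated test the unadjusted p was 0.00050, and the p adjusted over all 10405 genes was 0.0568, so Apaf1 missed the 0.05 threshold. The gene (ENSMUSG00000019979.12) lies on chromosome 10 of GRCm38 at 90989311 to 91082770 on the minus strand, and the table listed 2 of its protein-coding transcripts, of 6577 and 6433 bases with 27 exons each. The shares of the 2 transcripts moved between libraries of 1 group, the longer one being 1.21, 1.79 and 0.00134 in NC 1, 2 and 3, so only the sum was compared. Without NC 3 the adjusted p was 0.0439 with a log2 fold change of -1.11. Removing each library's trend with transcript length and GC content reduced the fold change to -0.60 with an adjusted p of 0.111. With a pseudocount of 0.1 or 0.01 it was -1.94 or -2.10, with adjusted p of 0.0723 and 0.0855. Apaf1 passed in 4 of 19 alternatives and missed the threshold in 15, where the adjusted p reached 0.234. The 4 were the one without NC 3, library weights whose fit did not converge (0.0015), and 2 chosen after the data were seen, gene-by-gene weights (0.0055) and rescaling without mitochondrial transcripts (0.0426).

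The intrinsic apoptosis list did not pass as a group, and its members went both ways. Of its 26 tested members 14 had positive and 12 negative fold changes, the median was 0.02, and the camera test gave an adjusted p of 0.646. Fry's test of changes in either direction gave an unadjusted p of 0.0224. That is not particular to apoptosis, since most tested lists were under 0.05 in the same test. Examples are p53 targets (0.0011), hypoxia and glycolysis (0.0037) and cell cycle S phase (0.0235), while heat shock (0.154) was not. No member passed over all genes, and Apaf1 alone passed when adjusted over the list alone (limma adjusted p 0.0131). Because the series names Apaf1 and may have chosen it on these libraries, that count is not independent evidence. The next members by p were Birc5, an inhibitor of apoptosis that also acts in mitosis, at 146 ± 15.1 (SD, n = 3) in NC and 234 ± 36.1 (SD, n = 3) in tRF-Val, and Diablo, an antagonist of such inhibitors, at 13.0 ± 5.86 and 27.6 ± 4.06. Endog, a mitochondrial nuclease, was at 2.44 ± 1.36 and 6.34 ± 2.37. The fold change of Casp9, which encodes the caspase activated on the Apaf1 scaffold, was -0.10, with an adjusted p of 0.847 by limma.

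Over all genes, 6 were higher and 21 lower in tRF-Val (limma, Benjamini-Hochberg adjusted p under 0.05, 10405 genes tested). Clcf1, a cytokine of the interleukin-6 family, was at 0.157 ± 0.237 (SD, n = 3) in NC and 7.43 ± 0.870 in tRF-Val, a log2 fold change of 2.88 with an adjusted p of 0.0117. Prpf19, a splicing factor and ubiquitin ligase, rose from 22.1 ± 4.46 to 107 ± 9.93, and Fdft1, the squalene synthase of sterol synthesis, rose from 19.0 ± 1.58 to 51.2 ± 2.36. Cadm1, a cell adhesion molecule, rose from 14.8 ± 0.456 to 37.6 ± 2.48. The remaining 2 were Stfa3, a cysteine protease inhibitor (log2 fold change 2.24), and Sprr2h, a small proline-rich protein (1.58). Both belong to families of closely similar genes, among which the authors' assembly may have divided reads, so their values are uncertain.

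Dtl, the substrate receptor of a ubiquitin ligase that limits DNA replication licensing, had the largest fitted fall among genes that passed with a pseudocount of 1. It was at 19.5, 18.6 and 16.8 in NC 1, 2 and 3, at 0.378 in tRF-Val 1 and listed at 0 in tRF-Val 2 and 3 (adjusted p 0.0031, limma). Stil, which acts in centriole duplication, was at 9.14, 7.41 and 9.98 in the NC libraries and listed at 0 in each tRF-Val library (adjusted p 0.0031). Whether these zeros are failed estimates was not tested. Values near 0 in 1 library alone did occur, as for mt-Nd4, a mitochondrial gene, at 0.494 in NC 1 and 1253 in NC 2. Values below 5% of a gene's median were counted among 3342 genes with a median of at least 20. They numbered 1, 1 and 5 in NC 1, 2 and 3. In tRF-Val 1, 2 and 3 they numbered 0, 7 and 3. No library listed more than 1 of these genes at 0. Dtl and Stil had medians under 20, so this count does not cover them. Of genes with an NC mean of at least 1, 19 were listed at 0 in every tRF-Val library, and 0 genes showed the reverse. Transcripts listed at 0 were more numerous in tRF-Val altogether, at 2013, 3081 and 2592 in tRF-Val 1, 2 and 3 against 1086, 1114 and 2199 in NC 1, 2 and 3. Golim4, a Golgi membrane protein, fell from 36.6 ± 8.79 (SD, n = 3) to 4.90 ± 2.30, and Ddx6, a helicase of processing bodies, fell from 26.7 ± 6.69 to 4.27 ± 1.25. Cdk13, a kinase that partners cyclin K, fell from 11.5 ± 0.355 to 1.23 ± 0.722, and Elmod2, which acts on small GTPases of the Arf family, fell from 5.21 ± 0.424 to 0.133 ± 0.0146. Log2 fold changes of the other named genes were -2.43 for Snrk, -2.32 for Apbb2, -1.95 for Aldh7a1, -1.86 for Azi2, -1.82 for Slx4 and -1.80 for Ifit2. Among them, Slx4 is a scaffold of DNA repair nucleases, Azi2 an adaptor of the TBK1 kinase and Ifit2 an interferon-induced gene. Other genes that fell included Ccn2 and, outside the rule for named genes, Svil, Fam208b, Pde4b, Pnpt1, Serpinb9, F3 and Dtx3l.

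On GRCm38, Dtl lies on chromosome 1 at 191537356 to 191575544 and Stil on chromosome 4 at 115000159 to 115043196. Clcf1 lies on chromosome 19 at 4214238 to 4223490, and Fdft1 on chromosome 14 at 63145150 to 63179578.

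**Figure D1:**
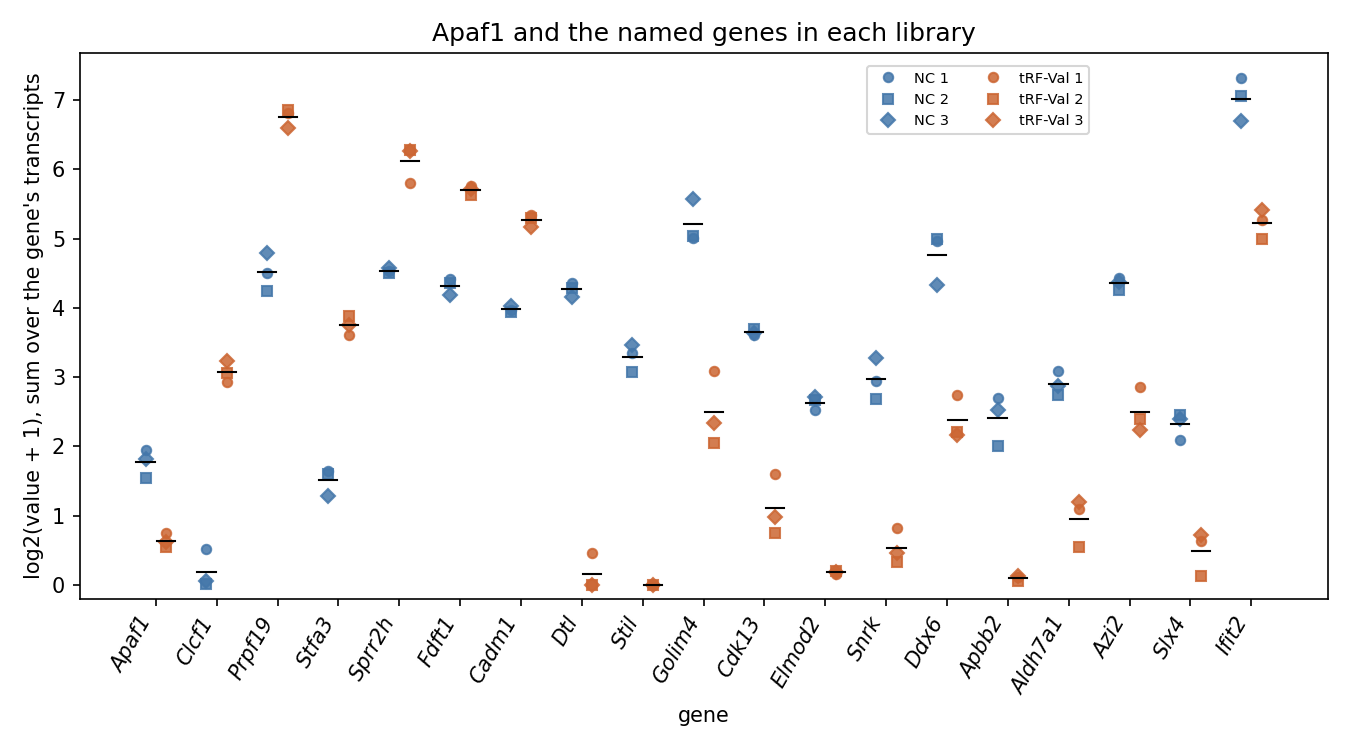
Values of Apaf1 and the 18 named genes in each library, as log2(value + 1) of the sum over a gene's transcripts; symbols are libraries and bars are group means of 3. The groups do not overlap in any gene shown, since the rule for named genes required it, and Apaf1 was added because the series names it.

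At an unadjusted p under 0.05, 1266 genes were higher and 1628 lower. The groups did not overlap in 42.5% of genes, where 10% is the chance for any single gene with 3 against 3. Genes of a library vary together, so the share in 1 split can lie far from 10%. That share was not computed for other splits, so it does not measure an effect of the group. The number of calls rested on single libraries. It was 284 higher and 309 lower without NC 3, sharing 6 and 20 genes with the calls over all libraries, and 0 higher and 4 lower without tRF-Val 2, or without tRF-Val 3. Without NC 1 it was 1 higher and 3 lower, without NC 2 it was 0 and 6, and without tRF-Val 1 it was 5 and 39. Dtl and Stil passed in each of these 6 fits. Scaling the libraries to a common median gave 19 higher and 25 lower, which moved the share of higher calls from 22.2% to 43.2%. Over single transcripts the same test called 49 higher and 137 lower.

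Genes of the interferon response were lower in tRF-Val as a list. Of 31 tested members 24 had negative fold changes, the median was -0.59, and camera gave an adjusted p of 0.00051 with a preset correlation and 0.892 with an estimated correlation. Fry gave an adjusted p of 0.225, so the list did not pass that test. Ifit2 passed over all genes, falling from 131 ± 27.5 (SD, n = 3) to 36.5 ± 5.41. Adjusted over the list alone, 11 members passed and all 11 were lower. Among these, Ddx58, a sensor of double-stranded RNA, fell from 68.7 ± 23.7 to 10.5 ± 5.76 (log2 fold change -2.67), Ifih1, another such sensor, fell from 44.2 ± 7.50 to 18.2 ± 3.54, and Parp14 fell from 50.3 ± 1.97 to 23.2 ± 4.00. Over the whole list, the groups did not overlap in 16 members that were lower and in 2 that were higher, Bst2 and Ccl5. The median of the list, centred on each gene's mean, was 0.516 and 0.410 in NC 1 and NC 2, 0.026 in NC 3, and -0.548, -0.274 and -0.068 in tRF-Val 1, 2 and 3.

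Genes of sterol synthesis were higher as a list. Of 22 tested members 19 had positive fold changes, with a median of 0.54 and an adjusted p of 0.0023 by camera (0.892 with an estimated correlation). By fry the adjusted p was 0.261. Fdft1 passed over all genes, and 3 members passed when adjusted over the list alone. These were Fdft1, Pmvk, the phosphomevalonate kinase (14.0 ± 3.36 to 29.8 ± 3.94, SD, n = 3), and Fdps, which makes farnesyl diphosphate (51.7 ± 22.7 to 134 ± 9.80). Insig1, a regulator of the pathway, was at 12.4 ± 3.62 and 21.9 ± 5.38 and did not pass. The list missed the threshold without tRF-Val 1 (median 0.32, adjusted p 0.0703). Its centred median was -0.829 in NC 3, below -0.044 in NC 1 and -0.072 in NC 2.

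Genes of TGF-beta signalling, matrix and the epithelial to mesenchymal transition were lower as a list, with a median of -0.46 over 19 tested members, of which 14 were negative. Camera gave an adjusted p of 0.0028, and 0.5001 with an estimated correlation, and fry gave 0.0202. The median was -0.30 without NC 1, -0.29 without NC 2 and -0.19 after correction for length and GC content, with camera adjusted p of 0.0043, 0.0051 and 0.0017. Ccn2, a matrix-associated growth factor, passed over all genes, falling from 83.4 ± 7.81 (SD, n = 3) to 33.0 ± 3.68. Adjusted over the list alone 7 members passed, all lower, among them Fn1, fibronectin (log2 fold change -3.01), Thbs1, thrombospondin 1 (48.0 ± 3.00 to 19.9 ± 6.23), and Zeb2, a transcription factor of that transition (3.83 ± 1.62 to 0.321 ± 0.110).

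Ribosomal protein genes and nuclear genes of oxidative phosphorylation were higher as lists. Each of the 75 ribosomal protein genes had a positive fold change, with a median of 0.70 and an adjusted p of 7.4e-16 by camera, and 27 of 29 oxidative phosphorylation genes were positive, with a median of 0.72 and an adjusted p of 1.1e-06. With an estimated correlation the adjusted p by camera was 0.892 for both lists, and by fry it was 0.128 for both. Without NC 3 the medians were 0.49 and 0.46, and with quantile normalization 0.27 and 0.46. Ribosomal protein transcripts took 12.9%, 13.0% and 9.58% of the values in NC 1, 2 and 3 and 14.9%, 17.98% and 17.1% in tRF-Val 1, 2 and 3. No member of either list passed over all genes. Adjusted over the list alone 11 oxidative phosphorylation genes passed, all higher, such as Ndufb5 (47.0 ± 5.43 to 93.2 ± 18.2, SD, n = 3), Cox5a (161 ± 20.8 to 272 ± 34.2), Cox6c (165 ± 22.9 to 257 ± 14.9) and Cox5b (90.3 ± 17.4 to 154 ± 15.7). None of the ribosomal protein genes did; those with the smallest p were Rps21, Rpl39, Rps15a and Rpl38, with fold changes of 0.87, 0.80, 0.79 and 0.85. Both lists consist of short transcripts, with median lengths of 830 and 1231 bases, and after correction for length and GC content the medians were 0.18 and 0.20 with adjusted p of 0.0532 and 0.0256. After correction for length alone they were 0.16 and 0.26 with adjusted p of 0.0575 and 0.0624, so whether the oxidative phosphorylation list passed depended on the correction.

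Genes of small RNA and tRNA processing were slightly lower as a list, with a median of -0.27 and 16 of 20 tested members negative (camera adjusted p 0.0250, and 0.892 with an estimated correlation; fry adjusted p 0.0202). No member passed over all genes or over the list alone. Xpo5, which exports microRNA precursors, was at 24.2 ± 2.20 (SD, n = 3) and 12.1 ± 2.86, Xpot, which exports transfer RNA, at 20.1 ± 0.954 and 14.1 ± 1.55, Ago2 at 8.74 ± 0.0813 and 5.96 ± 0.597, and Tnrc6b at 2.87 ± 0.206 and 1.91 ± 0.154. The call was lost in 8 of 20 alternatives, with camera adjusted p up to 0.809. Among these were the fits without NC 3 (median -0.26, adjusted p 0.0637), without tRF-Val 1 (-0.30, 0.0703) and without a filter on low values (-0.23, 0.0576). Others were library quality weights (-0.27, 0.0637) and correction for length and GC content (-0.05, 0.686).

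**Figure D2:**
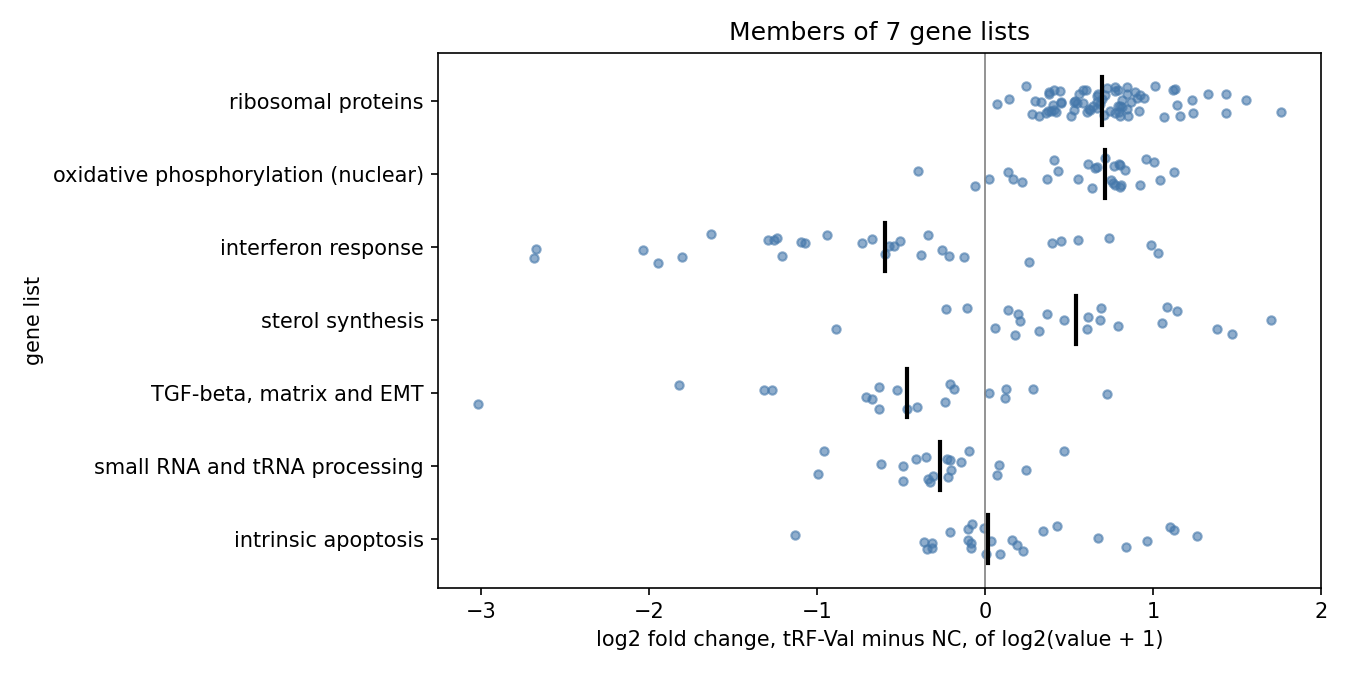
Log2 fold change, tRF-Val minus NC, of each tested member (points) of the 6 gene lists past the camera threshold and of the intrinsic apoptosis list; black bars are medians, and vertical scatter within a row has no meaning. Medians run from 0.72 for oxidative phosphorylation to -0.59 for the interferon response, and that of intrinsic apoptosis is 0.02.

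These 6 of 25 tested lists passed camera with a preset correlation of 0.01. With an estimated correlation 0 lists passed, with 1 list at an unadjusted p under 0.05. Other splits of the same 6 libraries gave between 3 and 8 lists with the preset correlation. At least 6 lists were called in 3 of 10 splits, the real one included, so as many calls can arise from regrouping the libraries. Mitochondrially encoded genes had a median of -0.97 and did not pass (adjusted p 0.104). Without NC 3 the median was -0.52, and after correction for length and GC content it was -1.08, with a camera adjusted p of 0.0013. Their largest difference was in mt-Atp6, at 3000, 3085 and 8929 in NC 1, 2 and 3 and at 618, 479 and 308 in tRF-Val 1, 2 and 3.

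The fold change of a gene depended on the length of its transcripts. Across 10405 genes Spearman's rho between fold change and length was -0.56, and with GC content it was 0.45, or 0.22 without NC 3. Among 10 bins of genes by length, in the bin with the shortest transcripts, of median length 846 bases, the median fold change was 0.61, and in the bin with the longest, of median length 7336 bases, it was -0.42. The relation with length had a rho of -0.56 without NC 3 and also in the 4979 genes with 1 listed transcript. The 21 genes that fell had a median length of 3818 bases and the 6 that rose 2234 bases, against 2795 bases over all genes tested. After correction for length and GC content 24 genes were higher and 35 lower, of which 4 and 14 were shared with the calls without correction. The calls lost were those of Prpf19, Sprr2h, Ddx6, Ifit2, Ccn2, Fam208b, Pnpt1, Serpinb9 and Dtx3l. The log2 fold change of Sprr2h went from 1.58 to 1.04, that of Fam208b from -1.39 to -0.76 and that of Dtx3l from -1.12 to -0.64. That of Prpf19 changed little, from 2.24 to 2.08, and that of Ccn2 grew, from -1.31 to -1.41. A lost call thus did not always come with a much smaller fold change.

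**Figure D3:**
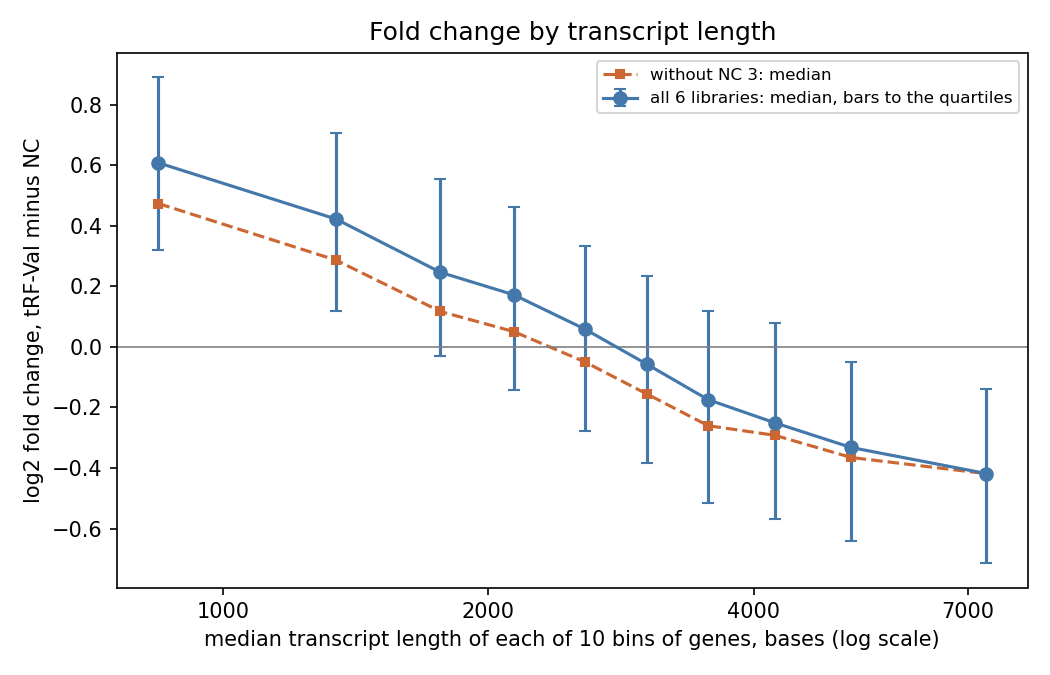
Median log2 fold change, tRF-Val minus NC, of genes in 10 bins of transcript length in bases (log scale); bars reach to the quartiles, and the dashed line gives medians without NC 3. The median falls from 0.61 in the shortest bin to -0.42 in the longest, and without NC 3 from 0.47 to -0.42.

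In each list of cell type markers, the line's own included, fewer were listed than not. Of 14 leukocyte markers 6 were listed, of which Cd14 was at 20.8, 18.9 and 5.40 in NC 1, 2 and 3 and at 37.1, 32.8 and 31.5 in tRF-Val 1, 2 and 3. Of 11 endothelial markers 4 were listed, with Cdh5 at 7.34 ± 0.960 (SD, n = 3) in NC and 3.57 ± 1.27 in tRF-Val, which passed as lower when adjusted over the list alone. Scx, a tendon and joint marker, was at 37.8 ± 14.5 and 77.3 ± 9.68. None of these passed over all genes. Also listed were 3 of 11 fibroblast, 4 of 15 joint, 1 of 12 muscle and fat, 3 of 19 other nephron segment and 5 of 21 proximal tubule markers. Of the proximal tubule markers, Slc4a4, a sodium bicarbonate cotransporter, was at 2.14 ± 0.296 and 0.920 ± 0.211 and passed over the list alone.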

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

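Apaf1, the named genes and the 6 list medians past the threshold kept their direction in each alternative run for them; single transcripts and the other called genes were not followed through every alternative. Among the 18 named genes beside Apaf1, 221 of 353 alternatives kept the call and 132 lost it, with 0 reversed. The number of genes called, 6 higher and 21 lower, moved with most choices, and except where stated the cause was not tested. A pseudocount of 0.1 gave 2 higher and 3 lower, and 0.01 gave 0 and 0 (limma; 2798 genes at an unadjusted p under 0.05). A mean of at least 5 gave 1 and 1, with fewer genes tested. Median scaling gave 19 higher, quantile normalization 22 and 49, and limma without trend and without robust moderation 38 lower. Transcripts in place of genes gave 49 and 137. For transcripts, a pseudocount of 0.01 gave 15 and 51, and a mean of at least 5 gave 7 and 12. Requiring a 2-fold change as well left 6 and 21 genes.

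Library quality weights gave 2340 higher and 3280 lower genes, and 1393 and 1868 transcripts, with Apaf1 at -0.96. The default method of these weights stopped before it converged, giving NC 2 a weight of 15.009 and NC 3 one of 0.0827, so these counts should not be relied on. The gene-by-gene method, added after the data were seen because of that failure, gave 1631 and 2426 genes, 1092 and 1453 transcripts and -1.09 for Apaf1, which passed, and weighted NC 3 by 0.103.

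With the replicate number as a block, 0 genes and 0 transcripts were called in either direction, with 2455 genes and 2468 transcripts at an unadjusted p under 0.05. Deviations of same-numbered libraries from their group means had correlations of -0.030, 0.016 and -0.0095, and no library correlated best with its own number. The deviations of the 3 libraries of a group sum to 0, and NC 3 dominates those of NC. Such correlations could hardly show a pairing, so whether the numbers pair the libraries is open.

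Leaving out each library in turn gave 0 to 284 genes higher and 3 to 309 lower, 13 to 152 transcripts higher and 31 to 254 lower, and Apaf1 at -1.24 to -1.04, past the threshold only without NC 3. Where 0 genes were higher, without NC 2, tRF-Val 2 or tRF-Val 3, an unadjusted p under 0.05 was met by 2396, 1615 and 1639 genes in either direction. Of alternatives chosen after the data were seen, correction for length gave 9 and 16 genes and for length and GC content 24 and 35. Rescaling without mitochondrial transcripts gave 23 and 186 genes and Apaf1, which passed, at -1.27, and shifted the median fold change over all genes from 0.013 to -0.20. Leaving out NC 3 together with the correction gave 66 and 59 genes, so that higher calls outnumbered lower ones, and 157 transcripts higher. Of the 6 gene lists past the threshold, 0 passed with an estimated correlation and 2 by fry, and the count ran from 4 to 9 in the other alternatives. A count-based tool was not run, since the values are not counts. The table gives no reads, so the limit that depth sets on any of these values is unknown.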

Other observations

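The tests of transcript length, of the correlations of NC 3, of the human rows, of 3' UTR words and of the splits for genes were chosen after the results they bear on were seen. Other gene lists with no call as a whole held members that passed when adjusted over the list alone. Chemokine genes Cxcl1, Cxcl2 and Cxcl5 rose from 356 ± 19.5, 55.4 ± 5.10 and 213 ± 34.3 (SD, n = 3) to 603 ± 54.5, 97.4 ± 3.31 and 459 ± 61.8, while Nfkb1, a subunit of the transcription factor NF-kB, fell from 23.7 ± 1.93 to 9.77 ± 3.56. Their list had 4 higher and 3 lower members and a camera adjusted p of 0.319. Of 24 p53 targets tested, Fas, a death receptor, and Ei24 rose (9.31 ± 1.03 to 20.9 ± 1.68 and 20.4 ± 1.13 to 39.7 ± 2.64), and Apaf1, Plk2 and Rrm2b fell. Lcn2, a tubule injury marker, rose from 496 ± 67.2 to 1119.9 ± 233, and Tnfsf10, a ligand of death receptors, fell from 2.36 ± 0.723 to 0.523 ± 0.179. None of these genes passed over all genes by limma.

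The other lists tested with camera had adjusted p of 0.319 or more. These were tubule injury markers, NRF2 targets, cell cycle G2/M, fatty acid oxidation, autophagy and lysosome, immediate early genes, proximal tubule markers, unfolded protein response, cell cycle S phase, integrated stress response, hypoxia and glycolysis, ferroptosis and iron, death receptor apoptosis, tRNA synthetases, p53 targets and heat shock. Among 10 splits of the 6 libraries into 3 and 3, the real one called 27 genes and 186 transcripts, and the highest of the other splits 0 genes and 14 transcripts. For gene lists the real split called 6, and 3 of the 10 splits gave as many, the highest other split giving 8. With 10 splits a share under 0.05 cannot be reached.

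Fold changes fell with transcript length. A difference between libraries that has nothing to do with the groups may account for part of it: tRF-Val 2 minus tRF-Val 1, both of 1 group, had a Spearman rho of -0.34 with length, against -0.03 for NC 2 minus NC 1. It was 0.20 and 0.22 for NC 3 minus NC 1 and NC 2, and -0.30 and 0.11 for tRF-Val 3 minus tRF-Val 1 and tRF-Val 2. The 9 pairs between groups, tRF-Val minus NC, had a rho of -0.52 to -0.38, each farther from 0 than any pair within a group, so how much of the trend such differences give is open. After correction for length and GC content 18 of the 27 called genes passed, so the average trend does not account for most calls. Median fold changes of the length bins ran only from 0.61 to -0.42, so such a correction could hardly remove larger fold changes. A length effect that is stronger in single genes was not tested and stays open. Over all 27 a median of 85.3% of the fold was left. Small RNA and tRNA processing genes lay at the 42.7th percentile of random lists of the same length and GC content, so their length is enough to give their median. Interferon response genes lay at percentile 0, TGF-beta and matrix genes at 0.5 and sterol synthesis genes at 100, outside the middle 95% of their matched lists. Members of matched lists were drawn independently, so those lists lack the shared movement of real members. The estimated correlation between members was 0.31 for interferon response, 0.50 for sterol synthesis and -0.04 for TGF-beta and matrix genes. It was 0.48 for ribosomal proteins and 0.40 for oxidative phosphorylation. Where it is high, the percentiles can overstate how far a list stands out. Ribosomal proteins lay at the 99.75th percentile and oxidative phosphorylation genes at the 99.99th, above the middle of the matched lists, which themselves had medians of 0.55 and 0.39; length may give most of the first and part of the second, and what remains is open. A shift between short and long transcripts by the fragment itself stays open and was not tested.

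NC 3 stood apart from NC 1 and NC 2, with a mean r of 0.909 against a lowest r of 0.953 in the other pairs within a group. Its larger mitochondrial share stays open as a cause: the mean r was 0.906 without those transcripts, but leaving out so few genes could hardly change it. A GC-dependent bias may be part of the difference, as NC 3 minus NC 1 had a rho of -0.64 with GC content, and correction raised the mean r to 0.941, still below 0.953. A tRF-Val library under an NC label is argued against by 463 of 593 genes (78.1%), called without NC 3, in which NC 3 lay nearer the NC mean. A different state of the cells in NC 3 stays open and was not tested.

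The rows with human IDs held 10.8% to 12.1% of the values in the NC libraries and 8.97% to 9.81% in the tRF-Val libraries. A single table of human and mouse transcripts under 1 filter is argued against by 1112 human rows below 0.5 in the mean of their higher group, where 0 mouse rows lie, and 99 human rows are 0 throughout. Rows left over from a longer human table are a candidate explanation, since the lowest human ID number is 480567 while the mouse IDs begin at 1. Human RNA in the cells was not tested, because human gene names were not used here, and no biological explanation was tested.

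If the fragment lowered genes by pairing with their 3' UTRs, a short word there may mark lower genes. Of 15979 words of 7 bases tested in 10076 genes, after correction for length and GC content, 1 marked lower genes past a familywise threshold (TACTGTA, in 1388 genes, log2 difference -0.070, permutation p = 0.031). But 3 words marked higher genes, the strongest with p = 0.001, the smallest that 1000 permutations can give (AGACAGG, log2 difference 0.078), so words pass in both directions and by small amounts. The sequence of the fragment was not used, and the test leaves this hypothesis open.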
